A study of Homo sapiens with 8 samples.

How the data were processed

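Gene expression was measured in the primary effusion lymphoma cell lines BC3 and BCBL1 after culture with 5 µM lenalidomide or with the solvent DMSO. Each of the 4 groups of line and treatment held 2 Illumina 1-colour bead arrays, 8 in all, labelled with Cy3 from total RNA. The series text describes the arrays of a group as technical replicates. p-values therefore measure the spread between arrays, not between cultures. The time of exposure is not given in the sources used here.

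The authors deposited a table of probe intensity values on a linear scale with no normalization between arrays, per the file headers and the values. It held 47323 probes and no detection p-values or negative control probes. A second deposited table held log2 values of the same arrays. The submitters' processing notes name limma and no other tool; the function and the offset they used are not given in the sources used here. Each log2 column had a rank correlation of 1 with a single column of the intensity table. All log2 columns had a median of 4.91 and spanned 4.25 to 15.52, a background-corrected and quantile-normalized scale as judged from the values. Their log base and scale were taken from these comparisons. Signal on single arrays is given as an intensity; the number of arrays limits the precision.

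The columns of the intensity table give the line and the treatment but no replicate number. Arrays of a group are called a and b here. By the rank correlation of 1, array a was replicate 1 of the log2 table in each group and array b replicate 2. The numbers alone pair nothing across groups. Whether the replicate numbers of the log2 table pair samples was tested, and the result is given with the alternatives. The files give no slide or scan batch.

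The intensity values were corrected with limma's normexp method with an offset of 50, quantile-normalized between arrays and taken to log2, with R 4.3.3 and limma 3.58.1. This step had been fixed before the data were examined for a table without detection p-values; the first choice, neqc with an offset of 16, needs them. A log2 change on this scale understates the change of dim genes, because the offset adds the same amount to both sides. Detection was rebuilt from each array, in place of the planned detection p. The background was described by the mode of an array's signals and the SD of the side below it, and a probe was above background where its signal passed the normal quantile for a p of 0.05. This replacement was chosen after seeing the data. Probes above background on both arrays of at least 1 group were kept: 24523 of 47322 probes, or 51.8%. A probe listed at 0 on an array was left out, 1 in all. For a gene that was not above background in the dimmer group, a fold is written as at least N-fold. That bound sets the brighter group's mean against the mean of, per array, the higher of the lowest signal above background and the probe's own signal.

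Probes were named through the platform annotation supplied with the series. Of the probes analysed, 30113 had 1 gene symbol, 8 had several and 17202 had none here. Symbols were looked up by gene identifier in a current RefSeq gene table, which held 30074 of them; the other 39 were kept as annotated. Among probes with 1 symbol that passed the filter (17577), the probe with the highest mean over the 8 arrays stood for its gene, which left 12864 genes. Another 6946 kept probes had no single symbol and were set aside for the closing section. No genome build is named for the array in the sources used here, so no coordinates are given.

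A limma model with a mean per group was fitted over all 8 arrays with empirical Bayes moderation (4 residual and 8.74 prior degrees of freedom). The contrasts were lenalidomide against DMSO in each line, the difference of these effects between lines, and BCBL1 against BC3 under DMSO. p-values were adjusted by Benjamini-Hochberg within a contrast, with a threshold of 0.05. Each adjusted p below is limma's, and ± gives the standard error of a log2 change from that model with n = 2 arrays per group. The lines have separate control arrays, so no control is shared between the within-line contrasts. A separate limma fit used the mean of the arrays of each group, so that the cell line was the replicate (n = 2 lines, 1 residual and 9 prior degrees of freedom). It is the fit that treats the arrays as technical.

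Fixed before the data were examined were 21 gene lists with 507 entries, of which 429 were tested, and the rule for the genes named. A gene in several lists counts as an entry in each. That rule took IKZF1, IKZF3, IRF4, MYC and CRBN always, and the 8 rising and 8 falling genes with the largest log2 change per line. It took the 10 genes in each direction with the largest smaller change of the 2 lines, and up to 4 called members per list. It took the 6 genes in each direction with the largest difference between lines, and the 8 highest in each line under DMSO. Genes without a usual symbol were skipped outside the lists. Genes named outside the rule are said to be chosen after their values were seen. For the lines under DMSO the lists were tested after the data were seen; the other list tests were fixed in advance. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 21 lists, with camera at an estimated correlation and fry beside it. Counts of list members are given over all genes tested and adjusted over the list alone.

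The pipeline was tested on simulated arrays made from each line's mean signals over both treatments and the spread within groups. It was run over 12241 genes, of which a random set had known changes. For the BC3 contrast it recovered 87.2% of genes changed by 2 on the log2 scale, 37.5% of those raised by 1 and 5.1% of those raised by 0.5. The fitted median for a true change of 1 was 0.65. For BCBL1 it recovered 72.2%, 18.2% and 0% of genes raised by 2, 1 and 0.5, and for the difference between lines 57.1% of genes changed by -2. In the BC3 contrast, among 12014 unchanged genes it called 7.

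Alternatives fixed in advance covered the background correction and offset, cyclic loess together with offset 16, median scaling, the log2 table in place of the intensities, no filter and a stricter filter, the rule for several probes of a gene and a fit over probes. They also covered a test against 1.2-fold, trend and robust moderation, array weights, fits within a line, other designs across lines, a 1.5-fold threshold and leaving out each array in turn. Added after seeing the data was the log2 table with the replicate number as a block. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.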

Results

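The series measured the RNA response of the B-cell lymphoma lines BC3 and BCBL1 to lenalidomide. Primary effusion lymphoma is a lymphoma of body cavities driven by Kaposi sarcoma herpesvirus, and both lines carry that virus. Lenalidomide binds cereblon, the substrate receptor of a ubiquitin ligase, and directs the transcription factors IKZF1 and IKZF3 to degradation. Each line had 2 arrays with 5 µM lenalidomide and 2 with DMSO. The arrays had median intensities of 137 to 153 and 47.0% to 51.2% of probes above background. Gene values of arrays of a group correlated with r of 0.994 to 0.995 across genes, against 0.988 to 0.990 between treatments of a line and 0.922 to 0.930 between lines. Genes are not independent replicates. The first principal component held 82.4% of the variance and separated the lines, and the next held 7.46% and separated lenalidomide from DMSO in both lines.

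The first question was what happened to the transcripts of the lenalidomide targets and of the genes downstream of them. IKZF1 rose in BCBL1, by 0.61 ± 0.14 on the log2 scale (adjusted p = 0.0347), and its value in BC3 was 0.19 ± 0.14 (adjusted p = 0.552). The IKZF1 call in BCBL1 held in 6 of 14 alternatives and in 2 of the 8 fits that left out an array (adjusted p up to 0.658). IKZF3 had values of -0.57 ± 0.17 in BC3 and -0.31 ± 0.17 in BCBL1 and passed the threshold in neither line (adjusted p = 0.0869 and 0.398). IRF4, a survival factor of plasma-cell tumours, had values of -0.22 ± 0.16 and -0.18 ± 0.16 (adjusted p = 0.537 and 0.635). MYC had values of -0.31 ± 0.13 and -0.32 ± 0.13 (adjusted p = 0.232 and 0.233). A dimmer MYC probe, which the rule for several probes set aside, gave -0.15 in BC3 and -0.92 in BCBL1, the latter with adjusted p = 0.00517 in the fit over probes. CRBN, which encodes cereblon, had values of -0.05 ± 0.12 and -0.10 ± 0.12 (adjusted p = 0.889 and 0.746). The list of this axis had 12 tested members, with 0 called in BC3 and IKZF1 as the 1 called in BCBL1; the counts adjusted over the list alone were 0 and 1. In BC3, 2 of the 12 had an unadjusted p under 0.05. Neither line passed limma's camera for this list (adjusted p = 0.992 and 0.883).

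In BC3 the genes with the largest changes rose. COXFA4L3, also known as C15orf48, rose by 4.27 ± 0.13 on the log2 scale, a 19.2-fold change. MGP, a matrix protein that inhibits calcification, rose by 3.54 ± 0.13, and the cell surface mucin MUC1 by 3.06 ± 0.14. S100A9 and S100A8, the subunits of calprotectin, rose by 2.92 ± 0.14 and 2.48 ± 0.15. The keratin gene KRT80, the protease inhibitor gene SLPI and the complement gene CFB rose by 2.39 ± 0.13, 2.10 ± 0.13 and 1.99 ± 0.12. Adjusted p for these 8 genes lay between 1.80e-09 and 1.03e-06.

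The largest falls in BC3 were smaller. GNG7, a G protein subunit gene, fell by 1.38 ± 0.13 and NPTX2, a secreted pentraxin gene, by 1.33 ± 0.11. DDN fell by 1.14 ± 0.13, CT45A6 by 1.10 ± 0.12, PLD6 by 1.00 ± 0.13, ACSS1 by 0.94 ± 0.13 and GDPD3 by 0.92 ± 0.13. CYTOR fell by 1.11 ± 0.14 on its brightest probe, while another CYTOR probe rose by 0.63 in BC3 and by 0.74 in BCBL1, so its direction is open. CT45A6 belongs to a family of near-identical copies that a probe may not tell apart. In all, 562 genes passed the threshold in BC3, 410 higher and 152 lower, of which 381 changed at least 1.5-fold. The count was 232 without DMSO array a, 206 without DMSO array b, 310 without lenalidomide array a and 226 without lenalidomide array b of BC3, with the lone array of a group assumed to vary like the others.

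Of the fixed lists, interferon-stimulated genes had the smallest camera p in BC3. Among 44 tested members, 16 rose and 0 fell, and 29 rose when adjusted over the list alone. IFITM3 and IFITM2, which restrict virus entry, rose by 1.94 ± 0.12 and 1.63 ± 0.15. PARP9 rose by 1.40 ± 0.12 and LGALS3BP by 0.88 ± 0.13. The list passed camera (adjusted p = 2.18e-22), and also gave adjusted p = 0.0169 with an estimated correlation. Of 12 MHC class II genes, 3 rose and 0 fell (8 rose when adjusted over the list alone), among them HLA-DMB by 0.66 ± 0.13 and HLA-DRA by 0.51 ± 0.12. That list gave camera adjusted p = 7.09e-07, and adjusted p = 0.0989 with an estimated correlation.

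Genes of ribosome biogenesis and metabolism that MYC induces were lower as a list in BC3. Of 37 members, 3 fell and 0 rose (5 fell when adjusted over the list alone): ODC1 by 0.74 ± 0.13, NOP16 by 0.72 ± 0.12 and SRM by 0.62 ± 0.12. The camera adjusted p was 7.86e-10, with adjusted p = 0.0169 with an estimated correlation. DNA replication and mitosis genes were lower too, with 2 of 41 members called in either adjustment, GINS2 (fell by 0.62 ± 0.13) and CCNA2 (fell by 0.49 ± 0.12). Their camera adjusted p was 5.34e-06, and adjusted p = 0.0479 with an estimated correlation. These are the 3 lists of BC3 that held with an estimated correlation. Of 19 plasma cell and immunoblast markers 5 fell and 0 rose (5 fell and 1 rose over the list alone), including TNFRSF17, the receptor BCMA, by 0.78 ± 0.12, FKBP11 by 0.70 ± 0.12, SLAMF7 by 0.62 ± 0.16 and JCHAIN by 0.59 ± 0.13. Their camera adjusted p was 0.00586, and adjusted p = 0.110 with an estimated correlation. Over 17 alternatives and left-out arrays the camera adjusted p of this list ran from 7.22e-04 to 0.113, the last without lenalidomide array b of BC3. The calls of SLAMF7 and CCNA2 in BC3, and of DNAJB9 and SREBF1 below, held in fewer than 50% of the settings tried.

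In BC3 CDKN1A, the cell cycle inhibitor p21, rose by 1.62 ± 0.14 (adjusted p = 1.38e-05) as the 1 called member of 11 in the list of cyclin-dependent kinase inhibitors and D-type cyclins (3 rose and 1 fell over the list alone; camera adjusted p = 0.150). TNFSF10, the death ligand TRAIL, rose by 1.54 ± 0.13 and BIRC2 by 0.73 ± 0.14, 2 of 20 genes of the BCL2 family and death receptor list (2 over the list alone; camera adjusted p = 0.0834). Of 20 p53 target genes, CDKN1A and RRM2B (0.67 ± 0.13) rose (2 over the list alone; camera adjusted p = 0.243). Of 21 immediate-early and heat-shock genes 4 rose (7 over the list alone), with KLF6 at 0.85 ± 0.13, JUN at 0.82 ± 0.14 and IER2 at 0.65 ± 0.12. That list gave camera adjusted p = 0.00586, and adjusted p = 0.206 with an estimated correlation. Of 24 glycolysis and hypoxia genes NDRG1 rose by 0.76 ± 0.11 and BNIP3 fell by 0.83 ± 0.14 (1 and 1 over the list alone). The list as a whole was lower (camera adjusted p = 0.0101, and adjusted p = 0.206 with an estimated correlation).

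Among NF-kB target genes 4 of 22 rose and 3 fell in BC3 (4 and 4 over the list alone; camera adjusted p = 0.682), with NFKBIZ at 0.95 ± 0.13, TNFAIP3 at 0.60 ± 0.14 and BCL3 at 0.58 ± 0.13. A dimmer NFKBIZ probe gave 0.04 in BC3 and 0.14 in BCBL1. Of 23 stress response genes of unfolded protein and amino acid shortage, 2 rose (3 over the list alone; camera adjusted p = 0.915), DDIT4 by 0.80 ± 0.11 and DNAJB9 by 0.49 ± 0.13. Of 24 cholesterol and fatty acid synthesis genes 2 rose (3 rose and 2 fell over the list alone; camera adjusted p = 0.971), ELOVL6 by 0.63 ± 0.12 and SREBF1 by 0.50 ± 0.12. Of 19 survival genes bound by IRF4, BATF rose by 0.61 ± 0.13 and SLAMF7 fell (1 and 1 over the list alone; camera adjusted p = 0.992). In BC3 the limma calls were 0 of 8 B-cell identity markers, 0 of 17 MHC class I and costimulation genes and 0 of 29 cytosolic ribosomal proteins. The counts over the list alone were also 0, and 1 gene of each list had an unadjusted p under 0.05. The camera adjusted p values were 0.469, 0.992 and 0.737.

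Markers of other cell types were tested beside these lists. In BC3, 3 of 8 tested myeloid markers rose (4 over the list alone), S100A9, S100A8 and CD68 (0.68 ± 0.14), with camera adjusted p = 2.54e-04, and adjusted p = 0.0748 with an estimated correlation. Its camera adjusted p ran from 3.77e-05 to 0.200 over the 17 settings, the last with the stricter filter. Of 8 epithelial, stromal and endothelial markers KRT8 rose by 1.87 ± 0.11 and CDH1 by 1.04 ± 0.14 (2 over the list alone; camera adjusted p = 0.0144, and adjusted p = 0.217 with an estimated correlation). Its camera adjusted p ran from 6.09e-04 to 0.0865 over the 17 settings, the last without DMSO array a of BC3. Of 9 T and NK cell markers CD2 rose by 0.62 ± 0.12 while GZMB fell by 0.88 ± 0.14 and CD3E by 0.52 ± 0.12 (1 and 2 over the list alone; camera adjusted p = 0.992).

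**Figure D1:**
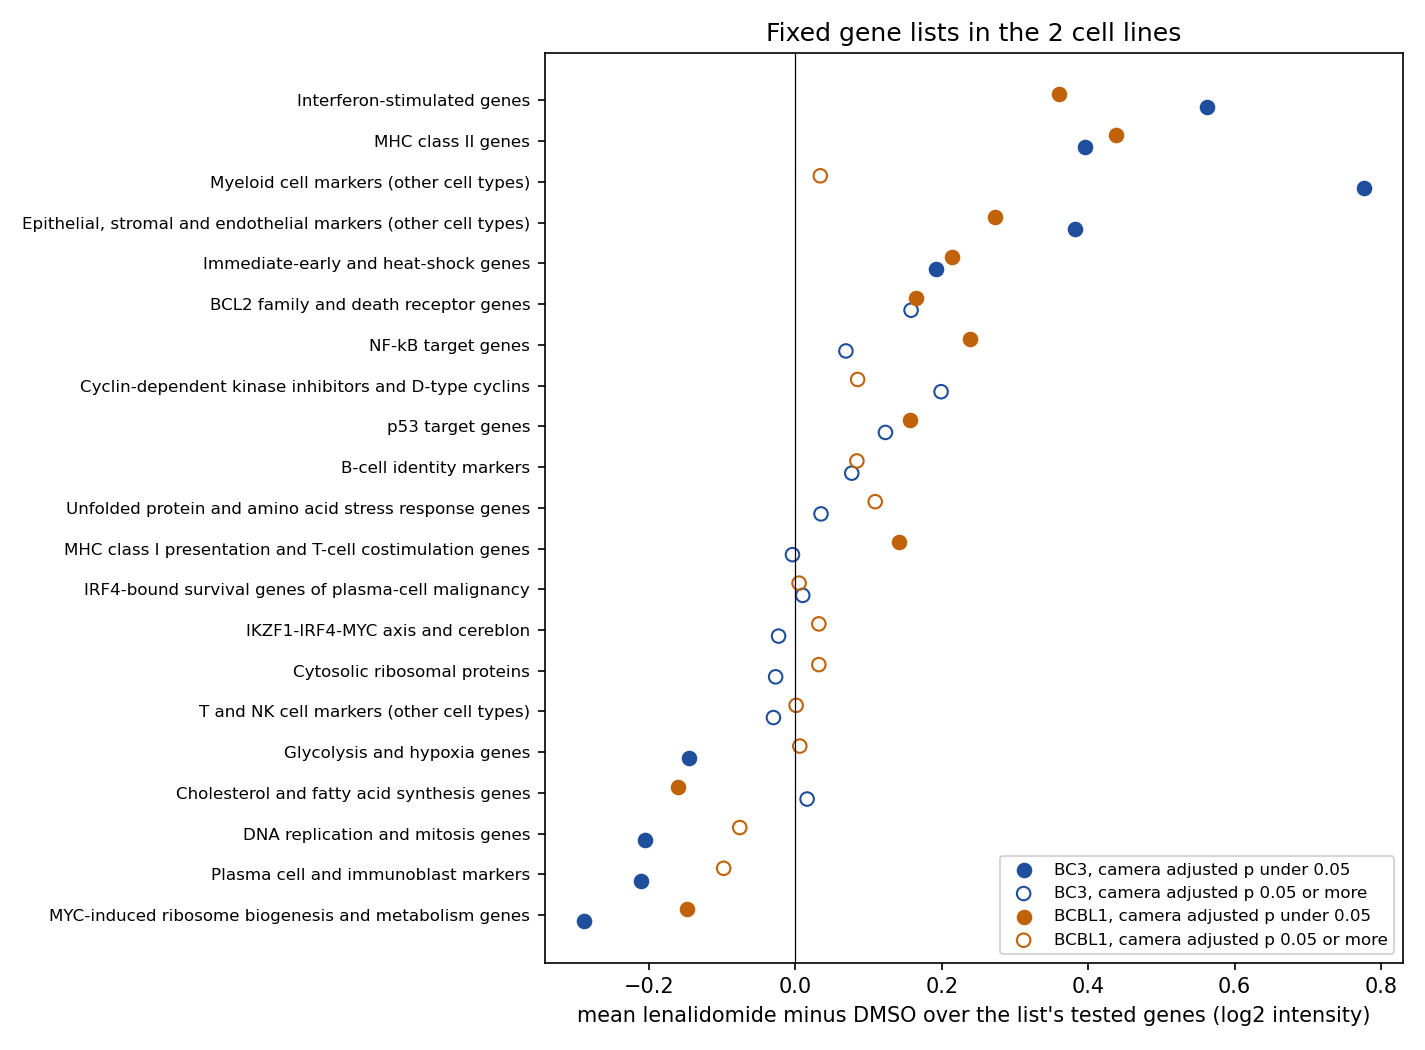
Mean log2 change with lenalidomide over the tested members of each fixed gene list, in BC3 (blue) and BCBL1 (orange), with filled points for lists past camera at the preset correlation. Interferon-stimulated genes had means of 0.56 in BC3 and 0.36 in BCBL1, and MYC-induced genes had means of -0.29 and -0.15.

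In BCBL1, MGP had the largest change, a rise of 6.17 ± 0.13 on the log2 scale or 72.2-fold (adjusted p = 1.19e-11). ATP6V1B1, a subunit of the vacuolar proton pump, rose by 3.27 ± 0.14. CDC42EP5 rose at least 3.79-fold from a level not above background. LGALS3BP and COXFA4L3 rose by 2.18 ± 0.13 and 2.12 ± 0.13. IFITM3, S100A2 and the GTPase gene RHOB rose by 2.08 ± 0.12, 2.01 ± 0.13 and 2.00 ± 0.19. The largest falls were NPTX2 by 1.41 ± 0.11, FKBP11 and GNG7 by 0.97 ± 0.12 and 0.96 ± 0.13, LGALS14 by 0.95 ± 0.12 and FAM81A by 0.95 ± 0.16. SSBP4 fell by 0.94 ± 0.15, FAM184A by 0.94 ± 0.15 and CMKLR2 by 0.87 ± 0.20. In all, 373 genes passed the threshold, 276 higher and 97 lower, 267 of them at least 1.5-fold. The count was 186 without DMSO array a, 195 without DMSO array b, 209 without lenalidomide array a and 151 without lenalidomide array b of BCBL1. With arrays scaled to a common median in place of quantile normalization, 141 genes were higher and 176 lower, or 44.5% higher against 74.0%. Cyclic loess in place of quantile normalization, run together with offset 16, gave 83.0%, and offset 16 alone 79.4%. Median scaling put the median change of all genes at -0.10. It used the median of all probes, which lay near the background threshold on each array.

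Interferon-stimulated genes were higher as a list in BCBL1 too. Of 44 members 12 rose and 1 fell (15 and 1 over the list alone), with IFITM3, LGALS3BP, IFITM2 (1.89 ± 0.15) and PARP9 (1.31 ± 0.12) changed most. The member that fell was ISG15, by 0.86, chosen after its value was seen. The camera adjusted p was 1.57e-08, and adjusted p = 0.0874 with an estimated correlation. Of 12 MHC class II genes 4 rose (9 rose and 1 fell over the list alone): CD74 by 1.07 ± 0.17, HLA-DRA by 0.99 ± 0.12, HLA-DMA by 0.71 ± 0.12 and HLA-DMB by 0.64 ± 0.13. Their camera adjusted p was 4.16e-07, and adjusted p = 0.112 with an estimated correlation. Of 22 NF-kB target genes 6 rose and 0 fell (9 over the list alone), including BCL3 by 1.25 ± 0.13, IRF1 by 0.61 ± 0.12, TNFAIP3 by 0.61 ± 0.14 and NFKBIZ by 0.56 ± 0.13. That list gave camera adjusted p = 4.25e-04, and adjusted p = 0.0874 with an estimated correlation.

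Immediate-early and heat-shock genes had 4 of 21 members higher and 1 lower in BCBL1 (7 and 1 over the list alone), with JUN at 1.54 ± 0.14, KLF6 at 0.73 ± 0.13 and ZFP36 at 0.52 ± 0.13. The member that fell was EGR1, by 0.81, chosen after its value was seen. The camera adjusted p was 0.00353, and adjusted p = 0.157 with an estimated correlation. Over 17 settings the camera adjusted p ran from 6.86e-04 to 0.0655, the last without DMSO array b of BCBL1. Of 20 BCL2 family and death receptor genes MCL1 rose by 0.53 ± 0.12 (3 over the list alone; camera adjusted p = 0.00845, and adjusted p = 0.131 with an estimated correlation). The camera adjusted p of this list ran from 0.00448 to 0.0629, the last without lenalidomide array a of BCBL1. CDKN1A rose by 1.10 ± 0.14 and RRM2B by 0.61 ± 0.13 among 20 p53 target genes (2 over the list alone). That list gave camera adjusted p = 0.0466, and adjusted p = 0.157 with an estimated correlation. It was past the threshold in 3 of 17 settings (0.0446 to 0.103) and lost in all 9 alternatives. CDKN1A was also the 1 called gene of 11 in the list of kinase inhibitors and D-type cyclins (1 over the list alone; camera adjusted p = 0.639).

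CD86 and ICAM1 rose by 0.50 ± 0.12 and 0.58 ± 0.13 among 17 MHC class I and costimulation genes in BCBL1 (2 over the list alone). The list gave camera adjusted p = 0.0262, and adjusted p = 0.156 with an estimated correlation. Its mean of 0.14 moved to -0.006 with median scaling, where the median of all genes was -0.10 (camera adjusted p = 0.288). Over 17 settings its camera adjusted p ran from 0.0104 to 0.288, and was 0.154 without DMSO array b and 0.114 without lenalidomide array a of BCBL1. Of 37 MYC-induced genes 0 were called by limma in BCBL1 (0 over the list alone, 7 with an unadjusted p under 0.05), yet the list was lower (camera adjusted p = 0.00113, and adjusted p = 0.0874 with an estimated correlation). Of 24 cholesterol and fatty acid synthesis genes 0 were called by limma (1 rose and 3 fell over the list alone, 10 with an unadjusted p under 0.05), and the list was lower (camera adjusted p = 0.00353, and adjusted p = 0.150 with an estimated correlation). The call of the cholesterol list was lost without lenalidomide array a of BCBL1 (camera adjusted p from 6.67e-04 to 0.100 over 17 settings). Without that array 5 lists passed camera in place of 10. With an estimated correlation 0 of the 10 held, while 6 lists had an unadjusted p under 0.05 by that test and 12 passed fry. The estimate lay under the preset 0.01 for NF-kB target genes (-0.014), MYC-induced genes (-0.011) and MHC class I and costimulation genes (0.002). It was -0.028 for BCL2 family and death receptor genes and for p53 target genes. The other lists had 0.024 (cholesterol) to 0.135 (MHC class II). A higher correlation cannot be why the lists under the preset were lost.

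Of 41 DNA replication and mitosis genes E2F2 rose by 0.53 ± 0.12 and GINS2 fell by 0.54 ± 0.13 (1 and 3 over the list alone; camera adjusted p = 0.111). Of 19 plasma cell and immunoblast markers 3 fell (1 rose and 4 fell over the list alone; camera adjusted p = 0.274), FKBP11, SLAMF7 by 0.87 ± 0.16 and TNFRSF17 by 0.64 ± 0.12. Of 19 survival genes bound by IRF4, KLF2 rose by 0.48 ± 0.11 and SLAMF7 fell (5 and 2 over the list alone; camera adjusted p = 0.883). BCL6 rose by 0.69 ± 0.13 as the 1 called gene of 8 B-cell identity markers (1 over the list alone; camera adjusted p = 0.621). DDIT4 rose by 1.28 ± 0.11 among 23 genes of the unfolded protein and amino acid stress response (1 over the list alone; camera adjusted p = 0.133). Of 24 glycolysis and hypoxia genes SLC2A3 rose by 1.05 ± 0.14, NDRG1 rose by 0.55 ± 0.11 and HK2 fell by 0.54 ± 0.12 (2 and 1 over the list alone; camera adjusted p = 0.883). Of 29 cytosolic ribosomal proteins 0 were called by limma (0 over the list alone, 1 with an unadjusted p under 0.05; camera adjusted p = 0.696). Of the markers of other cell types, KRT8 rose by 1.499 ± 0.113 and CDH1 at least 1.25-fold among 8 epithelial, stromal and endothelial markers (2 over the list alone), with camera adjusted p = 0.0363, and adjusted p = 0.240 with an estimated correlation. That list's call was lost in 5 of 17 settings (camera adjusted p from 0.00337 to 0.252). These were no background correction, no filter on dim probes, the mean of a gene's probes, and leaving out DMSO array b or lenalidomide array a of BCBL1. CD2 rose by 0.93 ± 0.12 among 9 T and NK cell markers (1 rose and 1 fell over the list alone; camera adjusted p = 0.883). Of 8 myeloid markers 0 were called by limma (1 over the list alone, 1 with an unadjusted p under 0.05; camera adjusted p = 0.883). The BCBL1 calls of KLF2, GINS2, E2F2, NFKBIZ, TNFAIP3, MCL1, CD86, ICAM1, HK2, ZFP36 and CDH1 held in fewer than 50% of the settings tried.

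The lines were then compared for genes that moved the same way. In both lines MGP, COXFA4L3, IFITM3, S100A2 (1.89 ± 0.13 in BC3), RHOB (1.85 ± 0.18 in BC3) and KRT80 (1.65 ± 0.13 in BCBL1) rose. IFITM2, MUC13 (1.60 ± 0.12 in BC3 and 1.58 ± 0.12 in BCBL1) and SMOX (1.66 ± 0.12 and 1.52 ± 0.12), a polyamine oxidase gene, rose as well. EMP1 rose at least 3.12-fold in BC3 and by 1.78 ± 0.22 on the log2 scale in BCBL1. NPTX2, GNG7, DDN, PLD6, LGALS14, STEAP1, FKBP11, MT1E, FAM81A and SAPCD2 fell in both lines, with the smaller of the 2 falls between 0.69 (SAPCD2) and 1.33 (NPTX2).

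In all, 135 genes rose in both lines, where independent lists of these sizes would share 8.80, and 29 fell in both, where they would share 1.15. Fisher's exact test across genes gave p = 6.68e-133 for the rises and 1.74e-33 for the falls, though genes are not independent replicates. Both contrasts also used 1 shared estimate of spread per gene, which favours the same genes in both lists. With each line fitted on its own 4 arrays, 121 genes changed the same way in both lines. The 2 genes that passed the threshold in opposite directions were NOC3L (-0.78 ± 0.15 in BC3 and 0.70 ± 0.15 in BCBL1) and TUBB3 (-0.60 ± 0.14 and 0.62 ± 0.14), the latter chosen after its values were seen. Across the 12864 genes the log2 changes of the lines had Pearson's r of 0.437 and Spearman's rho of 0.305. Of the 562 genes called in BC3, 86.1% had the same sign in BCBL1, and of the 373 called in BCBL1, 88.5% had the same sign in BC3. With any of the 8 arrays left out, 88 to 106 genes in place of 164 changed the same way in both lines.

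**Figure D2:**
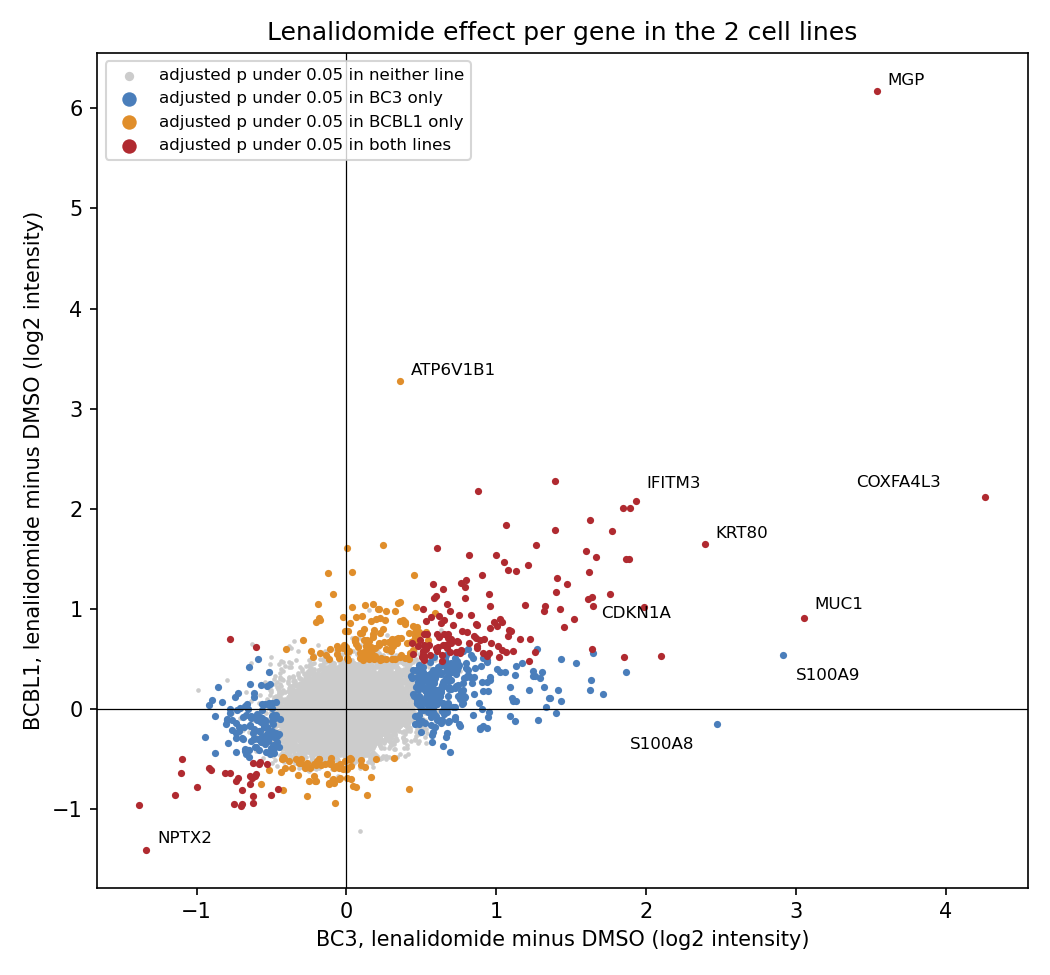
Log2 change with lenalidomide of each of 12864 genes in BC3 (x axis) and BCBL1 (y axis), coloured by the line in which limma's adjusted p was under 0.05. MGP (3.54 and 6.17) and COXFA4L3 (4.27 and 2.12) lie far from the rest, S100A8 and S100A9 lie near the x axis and ATP6V1B1 near the y axis.

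With the cell line as the replicate, IFITM3, S100A2, RHOB, EMP1 and IFITM2 had the smallest adjusted p among the genes named, from 3.89e-05 to 8.38e-05. CDKN1A (adjusted p = 8.09e-04), MGP (3.65e-04) and NPTX2 (1.97e-04) passed as well. IKZF1, IKZF3, IRF4, MYC and CRBN did not (adjusted p = 0.189, 0.114, 0.458, 0.222 and 0.828). In this fit 247 genes passed the threshold, 203 higher and 44 lower. The count rests on 1 residual degree of freedom and was 0 in limma with offset 16 and cyclic loess together or with the deposited log2 values, where 1487 and 1444 genes had an unadjusted p under 0.05. With offset 16 alone it was 20, and with median scaling 500. It was 48 without lenalidomide array a of BCBL1, 133 without DMSO array b of BCBL1 and 140 without DMSO array a of BC3.

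**Figure D3:**
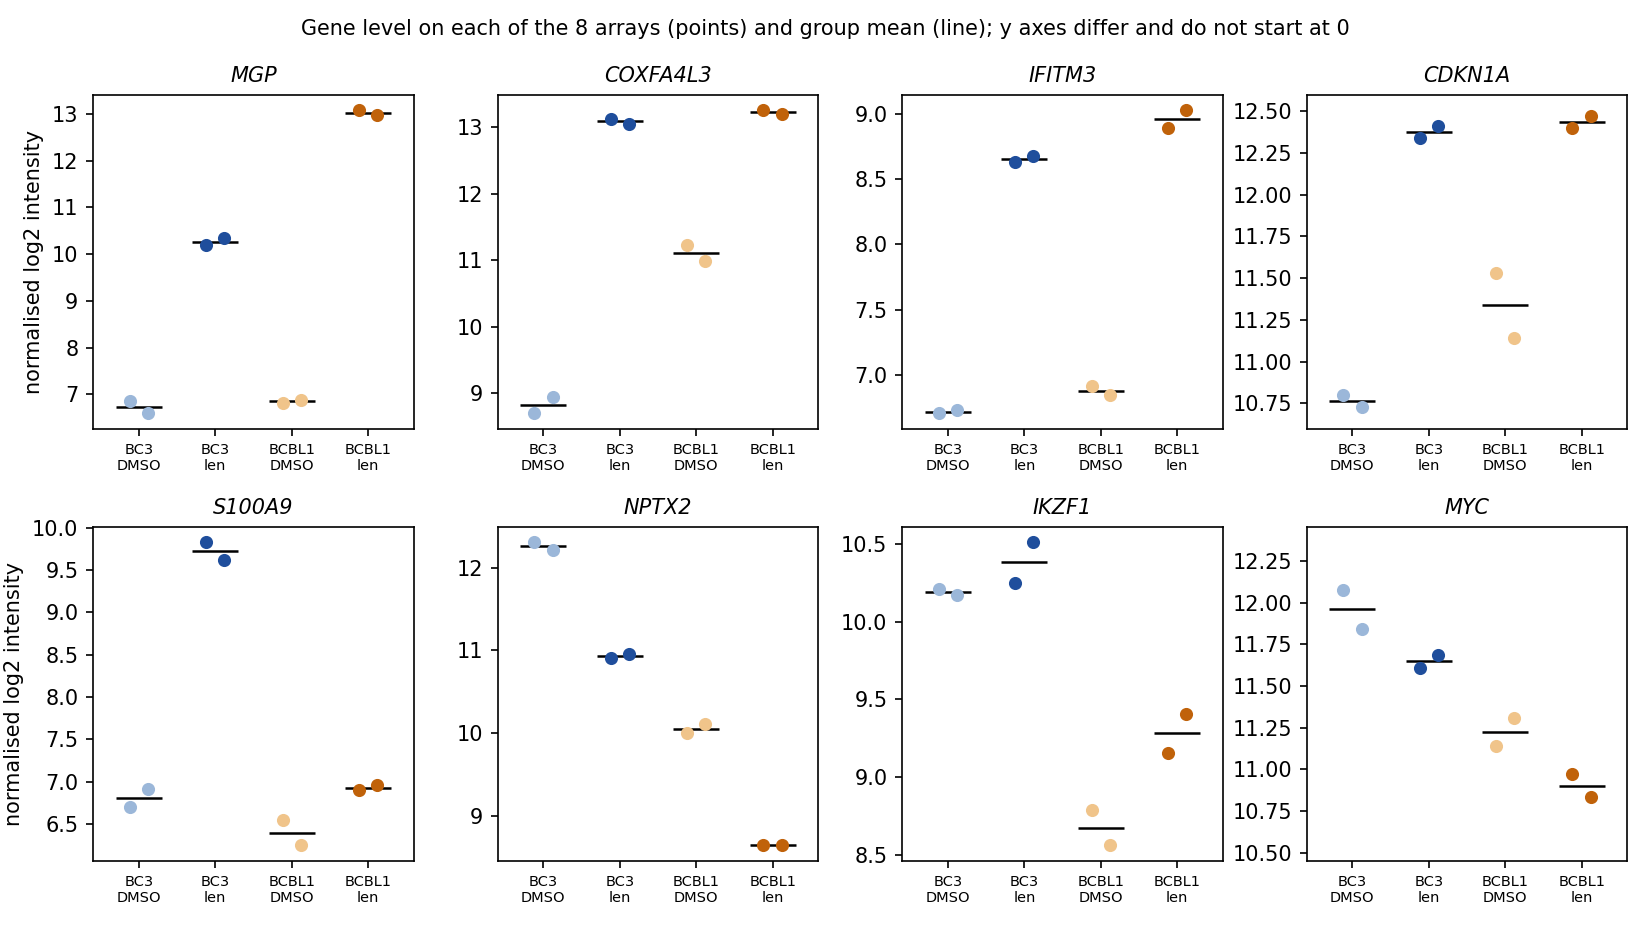
Normalised log2 intensity of 8 genes on each of the 8 arrays (points) with the group mean (line); len stands for lenalidomide, and the y axes differ and do not start at 0. In BC3, S100A9 moved from 6.70 and 6.92 under DMSO to 9.83 and 9.62 under lenalidomide, against 6.54 and 6.25 to 6.90 and 6.95 in BCBL1.

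Some responses differed between the lines. The effect was higher in BCBL1 than in BC3 for ATP6V1B1, by 2.91 ± 0.19 on the log2 scale, and for MGP by 2.63 ± 0.18. ARL14EPL differed by 1.48 ± 0.22. NOC3L, which fell in BC3 and rose in BCBL1, differed by 1.48 ± 0.22. FZD2, a Wnt receptor gene, passed the test too, but was not above background in BC3, so the size of its difference is not measured. TGM2 passed and rose at least 2.80-fold in BCBL1 from a level not above background, so its difference is not given as a value. The effect was higher in BC3 for S100A8 (difference of -2.63 ± 0.21), S100A9 (-2.38 ± 0.20) and COXFA4L3 (-2.15 ± 0.19). It was also higher there for MUC1 (-2.14 ± 0.20), SLPI (-1.57 ± 0.19) and UBD (-1.502 ± 0.204), a ubiquitin-like modifier gene. COXFA4L3, MUC1 and SLPI were already higher in BCBL1 under DMSO, by 2.29, 3.41 and 3.16. With lenalidomide COXFA4L3 reached 13.13 and 13.04 in BC3 and 13.25 and 13.19 in BCBL1, so the lines ended at similar levels. Under DMSO, BCBL1 minus BC3 was -0.08 for S100A8, -0.41 for S100A9 and -0.60 for UBD. S100A8 and S100A9 lay near background in BCBL1, and the sizes of their differences depend on the scale (-3.90 ± 0.37 and -2.81 ± 0.30 with the deposited log2 values). By the limma test of the difference 59 genes passed the threshold, 22 with a higher and 37 with a lower effect in BCBL1. The count was 25 without DMSO array a of BC3 and 30 to 36 without 4 other arrays (DMSO array b and lenalidomide array b of BC3, and lenalidomide arrays a and b of BCBL1).

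As lists, interferon-stimulated genes (mean difference -0.20) and myeloid markers (-0.74) had lower effects in BCBL1 than in BC3 by camera (adjusted p = 0.00110 and 5.49e-04), as had cholesterol and fatty acid synthesis genes (-0.18, adjusted p = 0.0135); each had adjusted p = 0.177 with an estimated correlation. MYC-induced genes (0.14), DNA replication and mitosis genes (0.13) and NF-kB target genes (0.17) had higher effects in BCBL1 (adjusted p = 0.0136, 0.0221 and 0.0136). With an estimated correlation 0 of these 6 lists passed (adjusted p = 0.177 for each with an estimated correlation), while 5 lists had an unadjusted p under 0.05 by that test and 2 passed fry. Over 17 settings the camera adjusted p of the myeloid list stayed at or under 0.0261. Its 2 called members of 8 were S100A8 (-2.63) and S100A9 (-2.38), so the mean of that list rests largely on these genes. The interferon list reached 0.322 with the stricter filter, the MYC and replication lists 0.105 and 0.267 with median scaling, and the NF-kB and cholesterol lists 0.0869 and 0.140 without lenalidomide array a of BCBL1. Without that array 2 lists passed camera.

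Under DMSO the lines differed in many genes. BCBL1 had higher levels of GNAS, a G protein subunit gene (6.28 ± 0.13 on the log2 scale). Another GNAS probe, near background (mean 6.32), gave -0.02, so that difference rests on 1 probe. ODAD3 (4.57 ± 0.18), SLFN11 (4.39 ± 0.12), CDCA7 (4.38 ± 0.13) and RRAGD (4.26 ± 0.14) were also higher in BCBL1. CLECL1, FZD2 and PNMA5 were at least 26.5-fold, 19.8-fold and 18.8-fold higher in BCBL1. BC3 had higher levels of BHLHE22 (by 6.55 ± 0.13, given as -6.55 for BCBL1 minus BC3), EPCAM (-6.17 ± 0.14), CLDN11 (-5.90 ± 0.15) and CD74 (-5.58 ± 0.17), the invariant chain of MHC class II. MGST2, PLBD1, IL13RA2 and FHL2 were at least 58.9-fold, 48.3-fold, 43.8-fold and 43.2-fold higher in BC3. In all 5213 genes passed the threshold, 2578 higher and 2635 lower in BCBL1, and 2966 of them differed at least 1.5-fold.

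The lists were compared between the lines after the data were seen. Of the 12 MHC class II genes 9 were lower in BCBL1 and 0 higher (9 over the list alone; camera adjusted p = 4.85e-07, and adjusted p = 0.113 with an estimated correlation), with HLA-DRA at -3.69 ± 0.12. Of 22 NF-kB target genes 15 were lower and 1 higher (15 and 1 over the list alone; camera adjusted p = 1.23e-05, and adjusted p = 0.113 with an estimated correlation). Of 44 interferon-stimulated genes 21 were lower and 4 higher (21 and 5 over the list alone; camera adjusted p = 4.10e-05, and adjusted p = 0.113 with an estimated correlation). Of 17 MHC class I and costimulation genes 11 were lower and 3 higher (12 and 3 over the list alone; camera adjusted p = 0.00294, and adjusted p = 0.113 with an estimated correlation), and of 9 T and NK cell markers 5 were lower and 1 higher (5 and 1 over the list alone; camera adjusted p = 0.0166, and adjusted p = 0.169 with an estimated correlation). With an estimated correlation 0 of these 5 lists passed, while 5 lists had an unadjusted p under 0.05 by that test and 16 passed fry. The call of T and NK cell markers was lost in 4 of 16 settings (camera adjusted p from 0.00616 to 0.189), among them offset 16 and leaving out DMSO array b of BC3. The lines are single cell lines, so this contrast compares BC3 with BCBL1 and no wider classes.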

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

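The limma and camera tests of the difference between lines were planned, and the tests of probes near background were set before their result was seen; the other tests in this part were chosen after the result was seen.

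The lenalidomide effect differed between the lines for 59 genes by limma's test of the difference itself. Among the genes named, the effect was higher in BCBL1 for ATP6V1B1 (difference of 2.91 on the log2 scale), MGP (2.63), ARL14EPL (1.48), LGALS3BP (1.30) and SLC2A3 (1.24), and for NOC3L (1.48), which fell in BC3 and rose in BCBL1. The fit also called FZD2 (1.60) and TGM2 (1.39), but FZD2 was not above background in BC3 and TGM2 not under DMSO in either line, so these sizes are not measured. The effect was higher in BC3 for S100A8 (-2.63), S100A9 (-2.38), COXFA4L3 (-2.15), MUC1 (-2.145), SLPI (-1.57), UBD (-1.502), TNFSF10 (-1.08) and CFB (-0.97). Of these, COXFA4L3, MUC1 and SLPI started from higher levels in BCBL1 under DMSO, by 2.29, 3.41 and 3.16. COXFA4L3 ended at similar levels in both lines with lenalidomide. S100A8 and S100A9 lay near background in BCBL1, and the sizes of their differences depend on the scale (-3.90 and -2.81 with the deposited log2 values). By camera, the mean difference was -0.20 for interferon-stimulated genes, 0.14 for MYC-induced genes and 0.13 for DNA replication and mitosis genes. It was 0.17 for NF-kB target genes, -0.18 for cholesterol and fatty acid synthesis genes and -0.74 for myeloid markers. The myeloid mean rests largely on S100A8 and S100A9. With an estimated correlation 0 of these 6 lists passed camera (adjusted p = 0.177 for each, 5 lists with an unadjusted p under 0.05), and fry passed 2, the MYC-induced genes and the myeloid markers. Outside the genes tested, 18 probes with no gene name here changed the same way in both lines, out of 71 called in BC3 and 59 in BCBL1.

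With the line as a term, 1 of the 34 splits of the 8 arrays gave as many calls as lenalidomide against DMSO. That was the real split, with 697 genes, and the highest of the other splits gave 0. Each other split put lenalidomide and DMSO arrays in the same arm, so a treatment effect widened its residual spread. Low counts there were nearly fixed in advance and do not test chance. The arrays are technical replicates, so the splits say nothing on chance differences between cultures, which stay open.

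More genes rose than fell with lenalidomide in both lines. Under quantile normalization, whether probes near background account for it stays open, because the split by brightness cannot decide it. Brightness was the mean over all arrays, lenalidomide arrays included, so a gene rising from near background could count as bright. MGP, for example, averaged 9.22 on the log2 scale over all arrays but 6.72 under DMSO in BC3. Among called genes brighter than the median gene, 69.9% rose in BC3 (n = 339, 95% binomial interval 64.7 to 74.7). In BCBL1 75.1% rose (n = 213, 68.8 to 80.8). The intervals in this paragraph treat genes as independent replicates, which they are not. In BC3 scaling between arrays stays open as a cause. The excess held there with median scaling, where 75.3% of 441 called genes rose (interval 71.0 to 79.2). Yet median scaling hardly moved the median change of all BC3 genes (-0.025, against -0.014 with quantile normalization), so it tested little. In BCBL1 that scaling left 44.5% of 317 calls rising (38.9 to 50.1), while cyclic loess, run together with offset 16, left 83.0% rising (79.4% with offset 16 alone), so the excess there depends on the scaling and its cause stays open. Median scaling used the median of all 47322 probes, which lay near the background threshold (intensity 144.5 against 146.3 on lenalidomide array b of BCBL1). It thus aligned the arrays on dim probes, and left the tested genes of BCBL1 with a median change of -0.105. Quantile normalization and median scaling rest on different assumptions, and no spiked control was used here to choose between them.

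S100A8 and S100A9 rose in BC3, with a higher effect than in BCBL1; myeloid cells in the lenalidomide samples would bring their other abundant transcripts, yet the 12 other markers had a median change of 0.148 in BC3 (quartiles -0.129 to 0.226), with LYZ (0.23) and TYROBP (-0.13) not above background, although CD68 among them rose by 0.68 on its brightest probe and by 1.85 on another. With each marker's most raised probe the median was also 0.148 (quartiles -0.056 to 0.226). Scaling between arrays did not end the difference: over median scaling, cyclic loess with offset 16 and 3 settings that keep quantile normalization, its highest adjusted p for either gene was 0.0281. With the deposited log2 values the S100A9 difference was -2.81 ± 0.30 (adjusted p = 0.0281), and adding the replicate number as a block left it at -2.81 ± 0.32 and ended the call (adjusted p = 0.0676, range of all settings 7.37e-06 to 0.0676), since the block takes a degree of freedom and the standard error rose. The S100A8 call held with that block (-3.90 ± 0.36, limma adjusted p = 0.0365). A response that differs between the cell lines is a hypothesis, and separate cultures were not compared.

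KRT8, KRT80, MUC1, MUC13 and CDH1, genes expressed in epithelial cells, rose in both lines, while KRT18, EPCAM, CLDN4, CLDN7, JUP and TJP1 were called in neither. The fixed list of such markers had 2 of 8 genes called in each line, and camera gave adjusted p = 0.217 in BC3 and 0.240 in BCBL1 with an estimated correlation. Epithelial cells in the samples would bring KRT18 and KRT19 with KRT8, and the highest change of either in either line was 0.278 ± 0.15 on the log2 scale (KRT19 in BC3, not above background in any group). A change of these genes within the lymphoma cells is a hypothesis; the genes were picked from these data.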

How the results depend on the processing

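The replicate block on the deposited log2 values was added after the data were seen; the other alternatives were planned. Among values of the called lists under other settings, 465 kept direction and call, 43 kept direction alone and 1 turned. Of 68 named calls in BC3, 32 passed in every setting, and of 67 in BCBL1, 29 did. Among all genes called in BC3, 177 had another kept probe, and for 112 of them no other probe was called. In BCBL1 these counts were 120 and 78. The cause of a moved value was not tested unless stated. A dim gene's change is limited by its signal over background. Slide as a block was not run, since the files give no slides.

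With offset 16 and cyclic loess limma called 362 genes in BC3, 200 in BCBL1, 23 for the difference, 98 in both lines and 0 across lines (1487 at an unadjusted p under 0.05), with r between the lines' changes of 0.386. With offset 16 alone these were 334, 194, 21, 91 and 20, with r of 0.382. The deposited log2 values gave 361, 219, 30, 93 and 0 (1444 unadjusted), with r of 0.383. Adding the replicate block to them gave 251, 144, 9 and 67, with r of 0.383. Same-numbered arrays deviated together with r of 0.046 in BC3 and 0.043 in BCBL1, so no pairing of the samples was seen. Median scaling gave 500 genes across lines and turned the mean of MHC class I and costimulation genes in BCBL1 to -0.006, where it moved the median of all genes. The correlation was 0.471 with no background correction, 0.366 with no filter and 0.524 with the stricter filter, which left 26 genes for the difference. A fit over probes gave 7992 probes between lines under DMSO and r of 0.377. The mean of a gene's probes turned CRBN (0.04) and CYTOR (0.117) in BCBL1, the latter because its probes disagree. Testing against 1.2-fold, a stricter null, left 143, 97, 25 and 2781 genes in the 4 contrasts, 46 in both lines and 64 across lines. At least 1.5-fold left 2966 under DMSO. Trend and robust moderation gave 423 across lines, all 8 arrays as replicates 934 and duplicateCorrelation 1197. The 4 arrays of BCBL1 alone gave 231. Camera with an estimated correlation passed 3 lists in BC3, 0 in BCBL1, 0 for the difference and 0 under DMSO, where fry passed 2 for the difference and 16 under DMSO.

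Leaving out 1 array, with a lone array assumed to vary like the other groups, gave 206 to 551 genes in BC3, 151 to 326 in BCBL1, 25 to 45 for the difference, 3873 to 5260 under DMSO, 88 to 106 in both lines and 48 to 356 across lines. The correlation was 0.386 to 0.424. Lists past camera were 8 to 9, 5 to 10, 2 to 8 and 4 to 5. IRF4 in BC3 ran from -0.481 to 0.037, turning without DMSO array a of BC3. CRBN in BC3 ran from -0.117 to 0.02, turning without DMSO array b. Neither was called.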

Other observations

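The gene groups in this part were all chosen after their values were seen. Guanylate-binding proteins, interferon-induced GTPases, rose in both lines in 4 of 5 tested genes. GBP4 rose by 1.88 in BC3 and 1.497 in BCBL1 on the log2 scale, GBP1 by 1.45 and 0.82, GBP2 by 1.00 and 1.54 and GBP6 by 0.64 in BC3 and 2.30-fold in BCBL1, while GBP5 did not pass limma's threshold in either line. Of 14 junction, adhesion, keratin, mucin, laminin and receptor genes expressed in epithelia 8 rose and 0 fell in each line, including CGN (1.62 in BC3 and 1.37 in BCBL1), ERBB3 (1.44 in BCBL1) and LAMB3 (0.68 and 0.70). The complement gene CFI rose by 1.08 and 1.38. Of 4 metallothioneins, which bind zinc and copper, MT1E fell in BC3, and MT1E, MT2A and MT1X fell in BCBL1 by 0.81, 0.81 and 0.57. Of 10 polyamine genes SMOX rose in both lines, while ODC1 and SRM fell in BC3.

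Under DMSO, 12 of 12 GAGE genes and 6 of 6 SSX genes, families of cancer-testis antigens, were lower in BCBL1 than in BC3 by limma. Of these, 8 GAGE and 3 SSX genes were not above background in BCBL1, so their differences are lower bounds, up to at least 23.7-fold for GAGE4. Members of these families are near-identical, and a probe that binds several of them cannot tell them apart, so the counts are uncertain.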
